A study of Mus musculus with 6 samples.

How the data were processed

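Bulk RNA sequencing of total RNA on an Illumina instrument, per the labels, was available for 6 libraries of mouse bone marrow-derived macrophages, 3 labelled Control (Cd74 wild type) and 3 labelled Cd74 knockout. Per the labels' protocols, marrow of 8-week-old mice was grown with 30 ng/mL M-CSF, the macrophage growth factor, and treated with 100 ng/mL lipopolysaccharide (LPS) for 24 h. The protocol text given with all 6 libraries speaks of wild-type mice, so genotype was read from the titles and genotype labels. Batch 1 held the 3 Control libraries and batch 2 the 3 knockout libraries, per the labels.

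The deposited table held 17217 rows of TPM, a length-scaled transcript abundance, for the 6 libraries, and 0 columns of per-sample values were left unmapped. The unit was read from the values, since the file header names none. Every column summed to between 991721 and 998572, and the low values of a row were whole multiples of a step set by the gene's length and the library. GRCm39 and DESeq2 are named per the submitters' processing notes, without a stated role, and the aligner, the counting tool and the annotation version were not given in the sources used here. The table carried 5 symbols on 2 rows each, and such rows were kept apart.

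Reads behind the TPM values were recovered by multiplying each value by a gene length and dividing by the library's step. Lengths were union exon lengths from GENCODE M21, an annotation of an earlier mouse build used for lengths alone, which held 16816 of the 17217 symbols. With a tolerance of 0.02 read, 16508 rows (95.9%) were whole in all 6 libraries at the annotated length. A search over other lengths with a tolerance of 0.003 read gave whole values for 681 more rows, and 28 rows were whole at no single length searched. The reach of that search was set before any of the 28 rows was known. A shorter reach of 100000 bp, run later for comparison, gave 29 such rows. The 1 row it added was Ttn, the giant muscle gene titin, whose length lay beyond that reach. Recovered depth was 36445462, 52517056 and 50523736 reads in Control replicates 1 to 3, and 59236599, 51726646 and 55680704 reads in knockout replicates 1 to 3. At these depths 1 read in a gene of 1 kb was worth 0.0558 to 0.0883 TPM. Of the values of 1 to 12 reads, 71.0% were even, against 51.2% among much higher values. On simulated data the recovery found the step of all 6 libraries. Among 3000 simulated rows it found 100 of 100 with rescaled knockout values and 100 of 100 with exchanged columns, and picked 0 unaltered rows wrongly. The 3000 rows had a mean of at least 100 reads and their true lengths were supplied, so unaltered rows were bound to be whole. Rows with fewer reads or without a known length were not simulated.

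Expression was compared with limma 3.58.1 in R 4.3.3 (lmFit, then eBayes with trend and robust settings) on log2(TPM + 1), with rows of mean TPM under 1 left out, which kept 13034 rows. Tests were two-sided, with Benjamini-Hochberg adjustment over all tested rows and a threshold of 0.05. Fold changes are on the log2(TPM + 1) scale, which understates the change of low genes. The design written before the data were examined named a count test, with limma-trend in its place for values other than counts unless whole reads could be recovered. Whole reads were recovered, but only by way of outside gene lengths and not for the 28 rows, among them Cd74. TPM values were therefore tested with limma-trend in this departure from the plan, and limma-voom on the recovered reads was run as an alternative. On simulated data of 13043 tested genes, limma called 54 of 66 tested genes changed 1.5-fold, 63 of 66 changed 2-fold and 60 of 62 changed 4-fold, and 15 of 12849 unchanged genes. Median estimates there were 0.52, 0.91 and 1.86 against true values of 0.58, 1 and 2. The simulated counts were drawn independently for each gene at a dispersion of 0.005, with no spread shared across the genes of a library. These rates hold for that setting and need not hold for the real libraries.

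Gene lists, 34 in all, were written before the data were examined, and the 29 with at least 3 tested members were tested with camera in limma at a preset correlation of 0.01, with Benjamini-Hochberg adjustment over the lists. Camera with an estimated correlation and fry were alternatives. With an estimated correlation, camera relies on few degrees of freedom, set by the 6 libraries, which costs power whatever the correlation. For the unfolded protein and integrated stress response list the estimate was -0.04, yet unadjusted camera p went from 1.4e-12 to 0.00148. For the cell cycle list the estimate was 0.80. A call lost in that setting therefore need not reflect correlation among genes. Named genes were chosen by a rule written at the same time: Cd74, then the 12 largest rises and the 12 largest falls among called genes whose mean TPM was in the upper part of tested rows (above the median of 20.2) and whose groups did not overlap, leaving out predicted genes and pseudogenes, then up to 4 members of each list with the smallest p. Cd74 is itself the largest fall. Any gene outside that rule is named as chosen after its values were seen.

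Other settings named before the data were examined were pseudocounts of 0.1 and 5, no filter, limma-voom on recovered reads, a replicate block, each library left out in turn, an estimated correlation and fry. Settings chosen after the data were seen were median-of-ratios and upper-quartile scaling of the TPM values, a filter of at least 1 TPM in at least 3 libraries, limma treat against a fold of 1.5, the table without the 28 rows (also with the other list tests), and the table without Control replicate 1 and knockout replicate 3 together. Figures and tables were made with Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9.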

Results

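RNA from LPS-treated cells labelled as bone marrow-derived macrophages was compared between 3 Control and 3 Cd74 knockout libraries. The question was how the transcriptome differs with loss of CD74, the invariant chain of MHC class II and a receptor for the cytokine MIF. Whether the cells are primary macrophages is taken up in the closing section. The libraries held 36445462 to 59236599 recovered reads, and 12854 to 13102 rows reached 1 TPM in each. The 10 highest rows took 11.8% to 13.5% of the TPM.

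Cd74, on chromosome 18, stood at 632, 593 and 594 TPM in Control replicates 1 to 3 and at 65.3, 64.6 and 63.1 TPM in knockout replicates 1 to 3. The means were 607 ± 22.2 and 64.4 ± 1.11 TPM (SD, n = 3 each), a 9.43-fold difference, and the log2 fold change was -3.22 (SE 0.05, limma adjusted p = 1.78e-07). The direction goes with the genotype labels in every library. The 3 Control values were whole reads at the gene's length, whereas 0 of the 3 knockout values were, and the rows beside Cd74 in the deposited table had a log2 ratio of -1.26 where the Cd74 row gave -3.24. The size of the Cd74 difference therefore rests on knockout values that are not read counts scaled like the other rows.

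Cd74 was 1 of 28 rows whose 6 values were not all whole at any single length. In 21 of these the 3 Control values were whole at the annotated length and the knockout values were not all whole, and in 19 of the 21, Cd74 among them, 0 knockout values were whole. The deposited rows ran in order of their knockout over control ratio (rank correlation 0.996 across rows). All 28 rows departed from that order by more than 0.25 on the log2 scale, against 1 (Alb, chosen after its values were seen) of the 13007 other rows with a mean of at least 1 TPM. As deposited all 28 were lower in the knockout, while 18 of them would be higher by their place among the rows. Genes of these 28 rows are marked below as not whole reads. The 28 also included, chosen after their values were seen, Gapdh, Ldha, Vegfa, Egfr and Nfatc4.

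**Figure D1:**
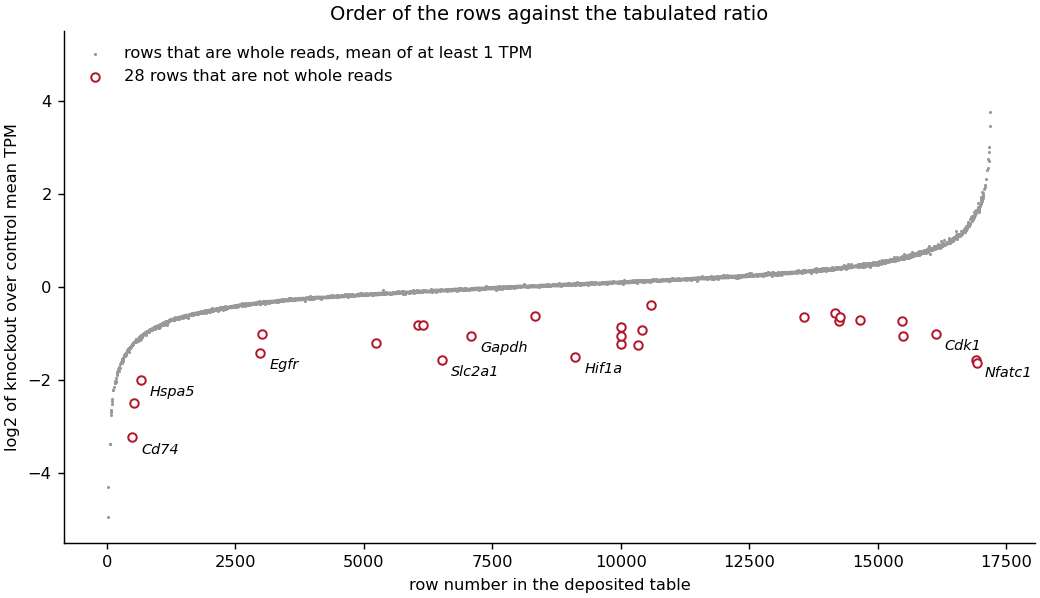
Each point is a row of the deposited table, with its row number on the x axis and the log2 ratio of knockout over control mean TPM on the y axis. Grey points are rows of whole reads with a mean of at least 1 TPM, and the 28 red circles are rows that are not whole reads, all of them below the curve of their neighbours.

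Without those rows, camera called the LPS-induced cytokine and stress response lists lower and the cell cycle and cholesterol synthesis lists higher in the knockout. With an estimated correlation the stress response list alone stayed past the threshold (adjusted p = 0.0494), and the other 3 lists each had adjusted p = 0.557. Il6, a fever-inducing cytokine, fell from 156 ± 5.55 to 43.2 ± 18 TPM (SD, n = 3 each), and the chemokine gene Ccl5 fell from 2647 ± 759 to 574 ± 229 TPM. Scin, which encodes the actin-severing protein scinderin, rose from 13.8 ± 2.75 to 60.9 ± 6.77 TPM. Of 13034 tested rows, limma called 2406 higher and 1313 lower in the knockout at an adjusted p under 0.05, and 161 of these moved by at least 1 on the log2 scale, 70 up and 91 down. Of the 91, 12 belong to the 28 rows, and without those rows 70 were up and 79 down. The share of higher calls was 64.7% as deposited and 51.5% after median-of-ratios scaling (1821 higher, 1715 lower), so the balance of directions depends on scaling. Groups did not overlap for 6519 of the 13034 tested genes. Chance gives 10% on average over splits of the libraries, but genes vary together, so a single split can lie far from it.

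All Control libraries were batch 1 and all knockout libraries batch 2, so batch and genotype cannot be told apart for any result here. The labels do not state that replicates came from separate animals or cultures, so p-values may measure technical spread.

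After Cd74, the largest falls were in Eno2, a glycolytic enolase (log2 fold change -2.46, SE 0.18, not whole reads, neighbours at -1.22), Ccl5 (-2.26, SE 0.33) and Hspa5, the endoplasmic reticulum chaperone BiP (-2.03, SE 0.18, not whole reads, neighbours at -1.07). Il6 (-1.93), Csf2 (-1.79), Il1a (-1.75), Fam171b (-1.74), Il1b (-1.66), the transcription factor gene Cebpb (-1.65), Il23a (-1.60) and the carbonic anhydrase gene Car6 (-1.57) followed. Il1b lost its call without Control replicate 1 or 3 and Il23a without Control replicate 1.

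The largest rises were in Scin (2.08, SE 0.14), Kbtbd11 (1.92, SE 0.06), the histone gene H4c9 (1.81, SE 0.12) and Angptl2, an angiopoietin-like secreted protein (1.59, SE 0.08). Csta3 (1.46), Il1f9 (1.31), Cstdc4 (1.31), the gelatinase gene Mmp9 (1.29), Mybl2 (1.17), the urokinase gene Plau (1.16), Ccne2 (1.15) and Pclaf (1.15) followed. Csta3 and Cstdc4 belong to a cluster of near-identical stefin genes and H4c9 to a family of near-identical histone genes, so their reads may have been shared among copies. These rankings follow the deposited directions, and that of Nfatc1 (-1.55, neighbours at 1.63) is in doubt. With its groups exchanged, the arrangement in which its 6 values are whole, Nfatc1 would stand at 1.55, rank 5 among the rises, and Pclaf would leave the 12.

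**Figure D2:**
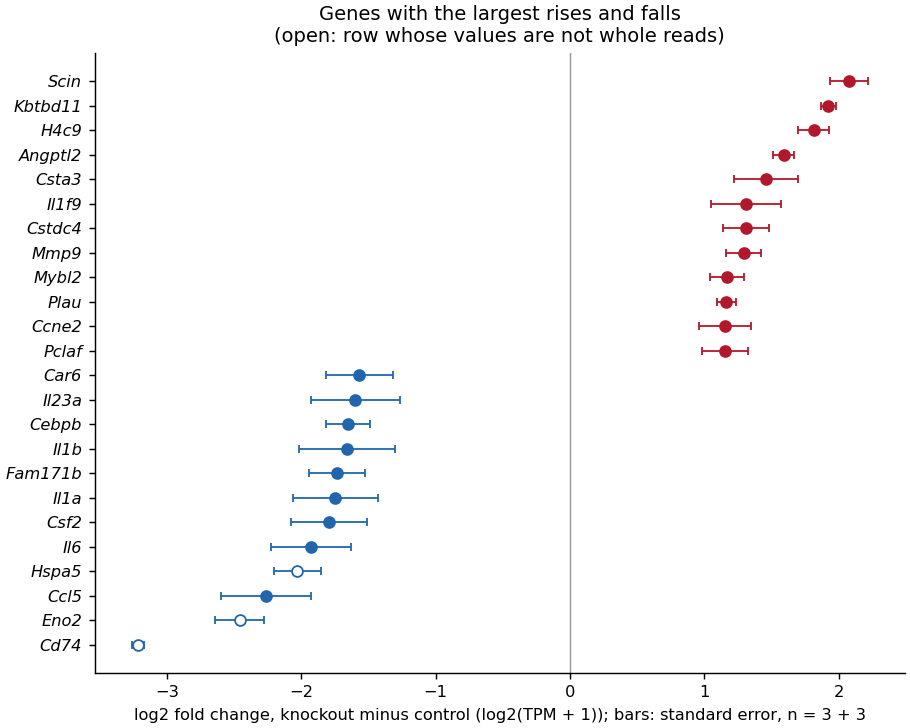
Points are limma log2 fold changes (knockout minus control, on the log2(TPM + 1) scale) with standard errors, n = 3 per group, for Cd74 and the genes with the largest rises and falls. Open circles mark Cd74, Eno2 and Hspa5, which belong to the 28 rows that are not whole at any single length.

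Of 20 tested LPS-induced cytokines and mediators, 0 rose, 15 fell and 5 were not called, with 15 falls adjusted over the list alone. Saa3, an acute-phase protein gene, fell from 110 ± 5.35 to 52.7 ± 4.06 TPM, Lcn2, which encodes an iron-sequestering lipocalin, from 950 ± 54.5 to 364 ± 90.1 TPM, and Tnf from 3513 ± 379 to 2012 ± 318 TPM (SD, n = 3 each). The list was lower by camera (adjusted p = 1.4e-07), with adjusted p = 0.526 with an estimated correlation. Among 15 chemokines 1 rose and 8 fell, and 6 were not called, with 1 rise and 11 falls adjusted over the list alone. Cxcl2 fell from 3735 ± 158 to 2039 ± 295 TPM and Ccl7 from 1330.5 ± 36.7 to 845 ± 89.2 TPM, while Cxcl3 rose from 2.62 ± 0.489 to 10.2 ± 3.04 TPM. The chemokine list was lower by camera, with adjusted p = 4.3e-04 and adjusted p = 0.526 with an estimated correlation.

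In the NF-kB pathway, which drives inflammatory transcription, 2 of 21 genes rose and 13 fell, with 2 rises and 17 falls adjusted over the list alone. Traf1 fell by 0.91, Nfkb2 by 0.68 and the feedback inhibitor gene Tnfaip3 by 0.47 on the log2 scale, while Nfkbid rose by 0.60. The list was lower (camera adjusted p = 9.7e-07), with adjusted p = 0.526 with an estimated correlation. Of 16 inflammasome and pyroptosis genes 2 rose, 6 fell and 8 were not called (3 and 6 adjusted over the list alone). Nlrp3, the sensor of the canonical inflammasome, fell by 0.39, Casp4 by 0.60 and Naip5 by 0.46. Naip5 lost its call without Control replicate 1, 2 or 3. Pycard, which encodes the inflammasome adaptor ASC, was too low to test, at 0 to 0.135 TPM (0 to 8 reads) in the 6 libraries, a gene chosen after its values were seen. Camera gave adjusted p = 0.0491 and adjusted p = 0.566 with an estimated correlation, and the call ended under both scalings and without Control replicate 3 or knockout replicate 3.

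Of 21 genes of the unfolded protein and integrated stress response, 0 rose, 16 fell and 5 were not called, with 19 falls adjusted over the list alone. Ppp1r15a, which restores translation after stress, fell from 345 ± 15 to 136 ± 28.1 TPM, Trib3 from 156 ± 8.12 to 87.5 ± 9.39 TPM and Herpud1 from 259 ± 9.90 to 161 ± 6.34 TPM (SD, n = 3 each). Hspa5 is the member that was not whole reads. The list was lower by camera (adjusted p = 3.9e-11), and this was the 1 list called with an estimated correlation (adjusted p = 0.0428).

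**Figure D3:**
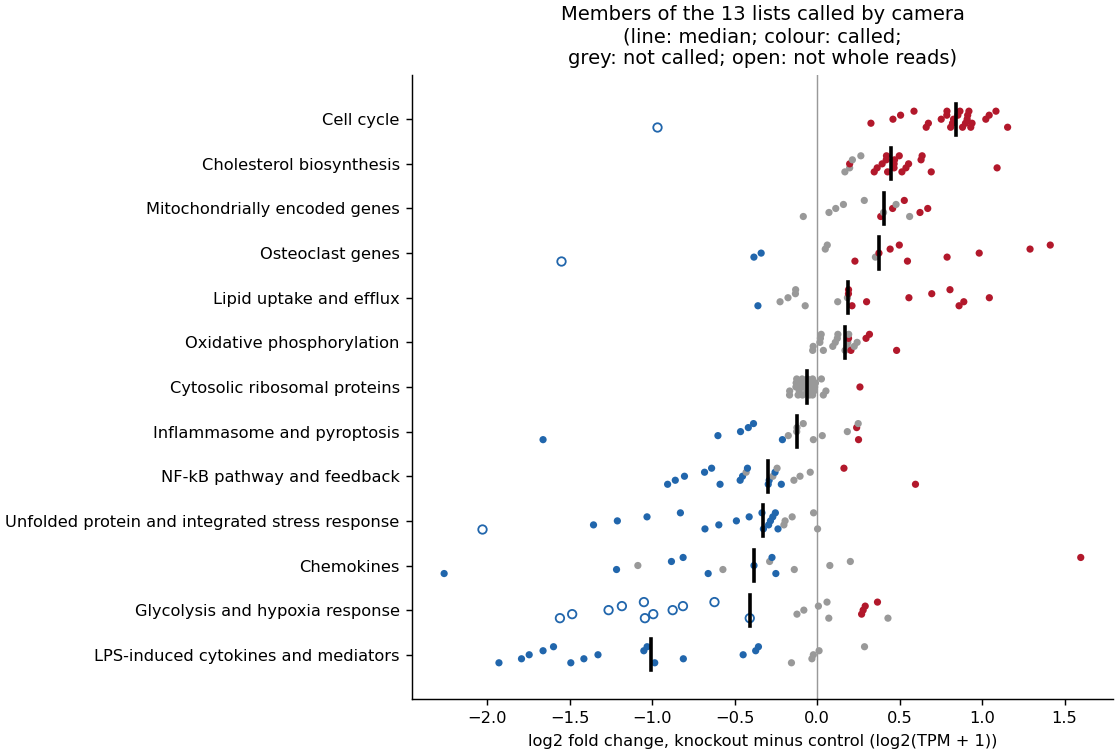
Each point is a tested member of 1 of the 13 lists called by camera, at its limma log2 fold change (knockout minus control), n = 3 per group. Coloured points passed the test, grey points did not, open circles are not whole reads and black lines are list medians, from -1.01 for the LPS-induced cytokines to 0.84 for the cell cycle.

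Of 26 cell cycle genes 25 rose, both over all genes and adjusted over the list alone. Ccnd1, the cyclin of entry into the cycle, rose from 103 ± 6.91 to 198 ± 22.1 TPM, the replication helicase gene Mcm7 from 50 ± 3.78 to 97.0 ± 10.7 TPM and the mitotic kinase gene Aurkb from 31.3 ± 1.60 to 58.9 ± 8.01 TPM (SD, n = 3 each). Cdk1 was the exception, at -0.97, and its knockout values were not whole reads while its neighbours in the table stood at 0.85. Camera gave adjusted p = 1.6e-10 and adjusted p = 0.526 with an estimated correlation.

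Of 22 cholesterol biosynthesis genes 18 rose and 0 fell, with 20 rises adjusted over the list alone. The kinase gene Pmvk rose by 0.47, Srebf2, the pathway's transcription factor gene, by 0.39 and Mvk by 0.35 on the log2 scale. The list was higher by camera (adjusted p = 1.4e-07), with adjusted p = 0.526 with an estimated correlation. Among 18 genes of lipid uptake and efflux 10 rose, 1 fell and 7 were not called (10 and 3 adjusted over the list alone). The sterol exporter gene Abcg1 rose by 0.89, the desaturase genes Scd2 and Scd1 by 1.04 and 0.69, and the fatty acid carrier gene Fabp4 by 0.81. This list was higher by camera, with adjusted p = 0.0317 and adjusted p = 0.471 with an estimated correlation.

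Of 21 genes of glycolysis and the hypoxia response 4 rose, 11 fell and 6 were not called (4 and 11 adjusted over the list alone), and all 11 that fell were not whole reads. Slc2a1, the glucose transporter gene GLUT1, was tabulated at a log2 fold change of -1.56 with neighbours at -0.07, Hif1a at -1.48 with neighbours at 0.07, Hk2 at -1.04 with neighbours at 0.11, and Pgk1 at -0.81 with neighbours at -0.09. The list was lower as deposited (camera adjusted p = 3.4e-04), with adjusted p = 0.341 with an estimated correlation. Without the 28 rows its median was 0.17. Camera then did not call it (adjusted p = 0.166, and adjusted p = 0.557 with an estimated correlation), while fry called it higher (adjusted p = 0.0212). The 10 members left then held 4 rises and 0 falls, and the rises, chosen after their values were seen, were Pgam1 (0.37), Slc16a3 (0.29), Pfkl (0.28) and Pkm (0.27). Pfkl and Slc16a3 lost their calls without Control replicate 1 or 3, and Pkm without Control replicate 3.

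Of 15 osteoclast genes 9 rose, 3 fell and 3 were not called, with the same numbers adjusted over the list alone. Car2 rose from 182 ± 8.00 to 361 ± 21.4 TPM, Fos from 28.2 ± 1.07 to 49.4 ± 1.24 TPM and Ocstamp, needed for osteoclast fusion, from 4.53 ± 0.370 to 13.7 ± 0.642 TPM (SD, n = 3 each). Nfatc1, the master regulator of osteoclasts, was tabulated at -1.55, with values that were not whole reads and neighbours at 1.63. Its 6 values became whole when the groups' library steps were exchanged. The osteoclast list was higher by camera, with adjusted p = 0.0283 and adjusted p = 0.471 with an estimated correlation. Without Nfatc1 and the other 27 rows, 9 members rose, 2 fell and 3 were not called, with camera adjusted p = 0.00390 and adjusted p = 0.356 with an estimated correlation.

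**Figure D4:**
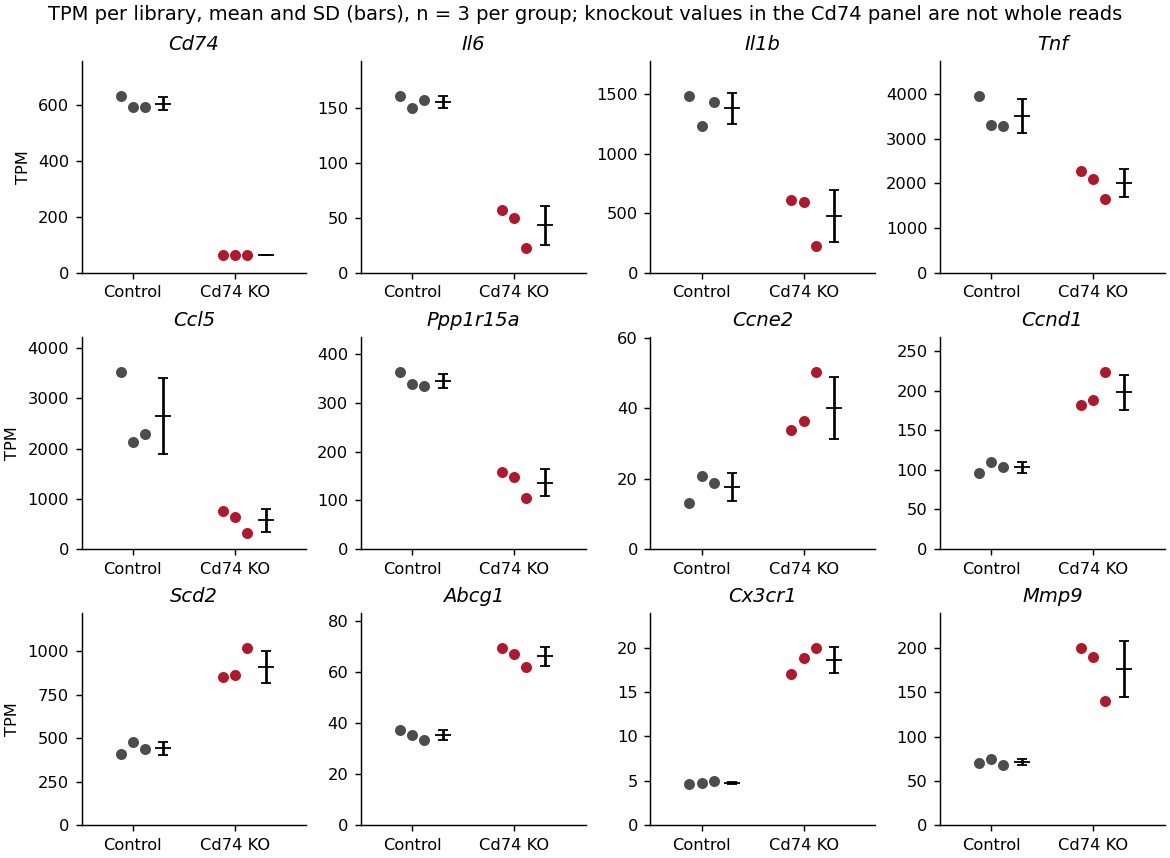
TPM of 12 genes in each library (points), with the mean and SD (bars) beside them, n = 3 per group, on axes that start at 0. Cd74, Il6, Il1b, Tnf, Ccl5 and Ppp1r15a were lower and Ccne2, Ccnd1, Scd2, Abcg1, Cx3cr1 and Mmp9 higher in every knockout library than in any Control library, and the knockout values of Cd74 are not whole reads.

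Of 21 oxidative phosphorylation genes 5 rose and 0 fell (4 and 0 adjusted over the list alone), with Sdhd up by 0.48 and Ndufb8 by 0.32. Ndufb8 lost its call without Control replicate 2 or 3. Camera gave adjusted p = 0.0140 and adjusted p = 0.566 with an estimated correlation. Of 13 mitochondrially encoded genes 5 rose and 0 fell (5 and 0 adjusted over the list alone). mt-Nd1 rose from 4143 ± 555 to 6644 ± 1397 TPM and mt-Nd3 from 1.39 ± 0.107 to 2.69 ± 0.255 TPM, and nuclear copies of mitochondrial genes may share such reads. The mt-Nd3 values stood near the filter of a mean of 1 TPM and far below those of mt-Nd1. mt-Nd1 lost its call without Control replicate 1 and mt-Nd3 under limma-voom. Camera gave adjusted p = 0.0278 and adjusted p = 0.579 with an estimated correlation, and the call ended without Control replicate 1 or knockout replicate 3. Of 28 cytosolic ribosomal protein genes 1 (Rpl37a, 0.26) rose and 0 fell, and 0 rose or fell adjusted over the list alone. The list as a whole was lower by camera, with a median of -0.06 (adjusted p = 0.0140, and adjusted p = 0.629 with an estimated correlation), a call that ended without Control replicate 1 or knockout replicate 1. Rpl37a lost its call when 5 of the 6 libraries were each left out in turn, and also under both scalings and with no filter.

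Classical class II genes were below 1 TPM in every library and were not tested, with at most 0.353 TPM of H2-Aa, 0.391 TPM of H2-Ab1 and 0.976 TPM of H2-Eb1, genes chosen after their values were seen. H2-Eb1 stood at 0, 0.128 and 0.0986 TPM in Control replicates 1 to 3 and at 0.976, 0.393 and 0.306 TPM in knockout replicates 1 to 3. The class II chaperone subunit gene H2-DMa was tested and not called, at 3.16 ± 0.760 and 3.77 ± 0.698 TPM (SD, n = 3 each). Of 3 tested members of the class II list 1 rose, Ifi30, a lysosomal thiol reductase gene (0.52), and camera did not call the list (adjusted p = 0.191). Of 5 tested MIF and CD74 partners 1 was called, Mif, at 0.19 (limma adjusted p = 0.0454), a call lost under limma-voom, both scalings, no filter and several left-out libraries, and 0 were called adjusted over the list alone (camera adjusted p = 0.822). Of 19 class I presentation genes 3 rose, 1 fell and 15 were not called (camera adjusted p = 0.647), with Tapbp up by 0.47 and Erap1 by 0.34.

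The macrophage identity list held 24 genes, of which 18 had a row and were tested. C1qa, C1qb, C1qc, Mertk and Maf, chosen after their values were seen, were among those without a row. Of the 18 genes 6 rose, 2 fell and 10 were not called (7 and 2 adjusted over the list alone, camera adjusted p = 0.288). Cx3cr1, the fractalkine receptor gene, rose from 4.74 ± 0.162 to 18.6 ± 1.46 TPM, the lysozyme gene Lyz2 from 5373 ± 355 to 8658 ± 778 TPM, and Adgre1, which encodes F4/80, fell from 489 ± 4.44 to 332 ± 34.0 TPM (SD, n = 3 each). All 3 tested neutrophil markers were called, S100a8 up by 1.73 and Lcn2 and Csf3r down by 1.41 and 0.62, and camera did not call the list (adjusted p = 0.398). Of 7 dendritic cell markers 1 rose, Bst2 (0.22), a call lost under upper-quartile scaling and without Control replicate 2 or knockout replicate 1 or 2 (camera adjusted p = 0.822). Too few members were tested for the other cell type lists. Ighm of B cells rose by 0.41, Lck of T cells and Hdc of mast cells fell by 0.25 and 1.73, and 0 of 1 erythroid and 0 of 2 stromal genes were called. Ighm lost its call without Control replicate 3 and Lck when 5 of the 6 libraries were each left out in turn, and also with a replicate block (which gave 2331 genes higher and 1380 lower in all).

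Genes listed as lying beside Cd74 on chromosome 18 went both ways, with 3 of 15 up, 3 down and 9 not called (camera adjusted p = 0.932). Among them were Csf1r, the M-CSF receptor gene, up by 0.76, and Ndst1, up by 0.42. The places of the listed genes were not checked, so some may lie elsewhere. Of the 4 tested sex-linked genes 0 rose and 2 fell (camera adjusted p = 0.0609).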

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

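The scalings, the filter by prevalence, limma treat, the removal of the 28 rows and the removal of 2 libraries together were chosen after the data were seen. The Cd74 log2 fold change was negative in every setting that gives one, at -3.27 to -3.14, and at -3.23 to -3.19 with 1 library left out in turn. Each of these settings used the deposited knockout values of Cd74 that are not whole reads, so this range does not check them. Limma-voom on recovered reads and the table without the 28 rows gave no Cd74 value. Leaving out 1 library gave 1312 to 2094 genes higher, 666 to 1222 lower, 5 to 6 lists higher and 6 to 9 lower: 1411 higher and 716 lower without Control replicate 1, 769 lower without Control replicate 2, 1312 and 666 without Control replicate 3, and 1585 and 872 without knockout replicate 2, where fewer samples give less power. Of 109 single genes 16 lost their call in at least 1 such fit, as did 3 of the 13 lists called in the main fit. Limma-voom called 1989 genes lower, and treat against a fold of 1.5 called 14 higher and 9 lower, since it asks for a larger change. An estimated correlation called 0 lists higher and 1 lower, and fry 10 higher and 3 lower. Fry ended the calls of the LPS-induced cytokines (adjusted p = 0.0555), chemokines (0.0577), inflammasome (0.190), ribosomal (0.168) and mitochondrially encoded (0.0555) lists, and called 5 that camera did not: class II (0.0215), lysosome (0.0207), matrix (0.00548), macrophage identity (0.00548) and immediate early (0.0168). Without the 28 rows these were 0 and 1, and 11 and 2. The glycolysis and hypoxia list turned from lower to higher under limma-voom (median 0.13), which has no reads for the 28 rows, and without the 28 rows (0.17 with camera, an estimated correlation and fry). Only fry called the turned list (adjusted p = 0.0212). Camera gave adjusted p = 0.198 under limma-voom and, without the 28 rows, 0.166 at the preset correlation and 0.557 with an estimated correlation. Without Control replicate 1 and knockout replicate 3 together 2347 were higher and 1355 lower. A replicate block gave 2331 higher and 1380 lower, with Cd74 at -3.22, and ended the call of Lck alone among the 109 genes. Replicate numbers did not pair the libraries (r across genes 0.13, -0.08 and 0.03 for the same number). Pseudocounts of 0.1 and 5 kept every call of the 109 genes and 29 lists. The planned edgeR and DESeq2 alternatives (other factors, a CPM filter, the Wald test, glmTreat) were not run. Recovered reads would have allowed them for 99.8% of rows, and limma-voom was the only count method run on those reads. Rows with a mean under 1 TPM were left out of the main fit by the chosen filter, not by depth. With no filter 17217 rows were tested, and 2161 were called higher and 1159 lower.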

Other observations

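Interferon-stimulated genes went both ways. Of 31 type I interferon-stimulated genes 5 rose, 6 fell and 20 were not called (5 and 7 adjusted over the list alone, camera adjusted p = 0.502): Oas2, an antiviral nucleotide synthetase gene, rose from 58.2 ± 2.71 to 96.3 ± 6.41 TPM, Trim30a rose by 0.50 and Usp18 by 0.33, while Oasl1 fell from 1245 ± 185 to 551 ± 117 TPM (SD, n = 3 each). Of 13 interferon-gamma-inducible GTPases and regulators 3 rose (Irgm1 by 0.71, Igtp by 0.49, Irgm2 by 0.42), 3 fell, among them Gbp5 by 1.71, and 7 were not called (camera adjusted p = 0.684). Of 21 Toll-like receptor genes 5 rose and 4 fell, with Tlr7 up by 0.59, Tlr13 up by 0.73 and the adaptor gene Ticam1 down by 0.54. That list's median was 0.02 and its mean -0.01 (camera adjusted p = 0.684).

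Of 17 immediate early and heat shock genes 6 rose and 4 fell, with Fos up by 0.79 and Dusp1 and Jund down by 0.75 and 0.64 (camera adjusted p = 0.822). Of 18 NRF2 and antioxidant genes 1 rose (Sod1, 0.28) and 4 fell, among them the haem oxygenase gene Hmox1 by 0.39 and the ferritin gene Fth1 by 0.35, with a median of 0.07 and a mean of -0.01 (camera adjusted p = 0.422). Of 23 lysosome genes 4 rose, Gusb by 0.32 and Lgmn by 0.36 among them, and 0 fell (camera adjusted p = 0.295), and Lgmn lost its call without Control replicate 3. Of 11 matrix genes 5 rose and 0 fell. Mmp12, macrophage elastase, rose from 3.95 ± 0.107 to 16.9 ± 0.501 TPM, and the urokinase receptor gene Plaur by 0.35. The list's median was -0.10, its mean 0.29 and its camera direction up (adjusted p = 0.372). Of 8 alternative activation genes 1 rose (Tgfb1, 0.28) and 2 fell (Ccl22 by 0.81, Klf4 by 0.73; camera adjusted p = 0.0733), and both falls lost their calls in some leave-one-out fits.

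All tests below were chosen after the results were seen, apart from that on Abl1, and Apoe, Pycard, Xist, Nfatc4, Prkca and Ccnd3 were named after their values were seen. The 28 rows that are not whole reads were all lower in the knockout as deposited. Printed precision does not account for them, since rounding allows an error of at most 0.00122 read in any value of the 27 rows with an annotated length, and another gene length in the knockout libraries was met by 3 of the 28 (1 with the shorter search of 100000 bp). Lower expression in the knockout and nothing else would leave rows in order, and 0 of the 28 were. Values changed after the rows were put in order remain open: 28 of 28 rows stand out of order, and the knockout columns sum to 6046 TPM less than the Control columns, where the rows' places imply 6182 missing TPM, but the table does not show how or why such a change came about. When the groups' library steps were exchanged, 2 of the rows (Nfatc1 and Nfatc4) were whole in all 6 values and 4 (with Prkca and Ccnd3) in at least 5, so the 28 need not share 1 origin.

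Of 12 genes of primary macrophages 6 had a row. C1qa, C1qb, C1qc, Mertk, Maf and Cd163, also named after their values were seen, had none. Apoe was highest at 4.03 TPM, and Pycard, a general inflammasome adaptor gene and not a marker of resident cells, had at most 0.135 TPM. Of the 12 genes 0 had a mean of at least 10 TPM. For primary macrophages as labelled this count of 0 leaves the question open, since LPS can lower several of these genes, though Pycard is not known as one of them, and untreated cells were not analysed here. A macrophage line transformed by Abelson virus, such as the male line RAW 264.7, which lacks ASC, also stays open: Pycard near 0, Ddx3y at 36.6 to 47.7 TPM and Xist at no more than 0.0640 TPM go with it, as the last pair would with any male cells. Abl1, which that virus carries, reached at most 15.4 TPM, under a bound of 50 TPM set before the value was seen, but the bound was assumed and no library of such a line was measured, so the value excludes nothing.

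Lower inflammatory and higher cell cycle genes in the knockout may reflect genotype, as the design names, or batch, since 0 batches held both genotypes, and these cannot be told apart. Control replicate 1 and knockout replicate 3 stood farthest out on the first principal component (-27.1 and 31.4, 57.4% of variance). That component also set the groups apart, with Control replicates 2 and 3 at -14.1 and -16.2 and knockout replicates 1 and 2 at 11.6 and 14.5. Libraries of the same genotype and batch thus differed along the axis between the groups. Yet without both outer libraries, 3124 of the 3719 genes were called in the same direction, which argues against these 2 libraries alone. Of the 10 splits of the 6 libraries 1, the real one, gave as many as 3719 genes (highest other 0), and 1 gave as many as 13 lists (highest other 12). With 10 splits the share cannot fall under 0.05.

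Hepatocyte genes, chosen after their values were seen, summed to 66.8 TPM in Control replicate 1 and to 5.61 to 10.6 TPM in the other libraries. Of 18 such genes 16 had a row, and all 16 were highest in Control replicate 1. Since the genes were chosen after their values were seen, that count is not an independent test.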
